A study of Mus musculus with 4 samples.

How the data were processed

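Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Pitx1 on DNA from hindlimb buds of wild-type ICR mouse embryos at embryonic day 11.5. Pitx1 is a homeodomain transcription factor that is made in the developing hindlimb and not in the forelimb. The series holds 4 libraries: 2 Pitx1 ChIP libraries and 2 libraries of input chromatin, which was not immunoprecipitated. Per the labels' protocols, buds were fixed in 1% formaldehyde for 30 minutes and treated with trypsin for 5 minutes. The chromatin was then sheared to 200 to 600 bp, and 400 μg was incubated with the antibody. Material from 3 ChIPs went into the libraries. The labels do not say whether replicates 1 and 2 came from separate litters, so differences between them may be technical.

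Per the submitters' processing notes, the tools were CASAVA 1.7 and 1.8.2, Bowtie 0.12.8, MACS 1.4.2 and bedtools 2.16.2, and the genome build was mm9. The notes list these names without roles, and the peak caller's settings and its use of the input are not given in the sources used here. Peaks in each ChIP library's deposited list are numbered from the first upward under MACS names, so the lists come from separate calls and not from pooled reads. The deposited peak score is the caller's own value for each peak. By that caller's usual convention it is proportional to the negative logarithm of the peak's p-value, but the lists have no header that says so. Scores were mainly used to rank or split peaks within their own list, or as ranks between lists. Score values themselves enter the correlation of log10 scores between the lists and a comparison of chromosome X with a doubled score threshold. The lowest scores were 50.0 in replicate 1 and 50.01 in replicate 2. A further deposited list holds 1 bp positions with no score, and how it was made is not given in the sources used here. Whether the copy used here is complete is not known. Read counts were not used here, so the depth of each library is unknown and no value rests on a known number of reads. The input libraries had no list of their own and enter only through whatever the caller did with them.

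A peak was called shared when it overlapped a peak of the other replicate by at least 1 bp. A replicated peak is the union of peaks that overlap between the replicates. The chance of overlap was taken from 1000 rotations of one list within its chromosomes, each over the span from the first to the last peak, with a one-sided permutation test whose smallest p is 0.001. Rotation keeps the spacing of peaks but not regions that cannot be mapped. Peak density per chromosome was computed over the length up to the last peak, with 95% exact Poisson intervals. These and the 95% binomial intervals (Wilson) cover counting error only, and are too narrow where peaks cluster. A cluster is a run of 3 or more replicated peaks with midpoints under 10 kb apart, and was compared with 1000 uniform placements. Scores of peaks paired 1 to 1 were compared by Spearman's rank correlation across peaks, which are not independent replicates, with an interval from 1000 bootstrap draws. The regions named in the text were set by a rule fixed before the data were examined. They are the 10 replicated peaks with the lowest sum of ranks in the lists and the 5 densest windows of 200 kb. The strongest unshared peak of each replicate, the largest cluster and a chromosome 6 peak at 51121131 were outside that rule and were chosen after their values were seen.

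On simulated lists with 14685 peaks in the smaller list, where 50.0% of its peaks were planted in the other, 50.7% were called shared. Unrelated simulated lists shared 1.32% (permutation p = 0.791). Of 100 planted clusters, 99 were gained in the count. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were stricter score thresholds, equal numbers of peaks, other definitions of a shared peak, other gaps, uniform placement, each replicate alone, and the list of positions in place of the replicated peaks.

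The gene annotation at hand was of another build (GRCm38), and in 7 chromosomes the peaks reach beyond its last gene. Positions were not converted between builds. Peaks are therefore given by mm9 coordinates, counted from 1, without gene names. The planned tests of peak positions relative to genes, of limb gene lists and of sequence motifs were not run.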

Results

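Pitx1 peaks in embryonic hindlimb buds were available for 2 ChIP libraries. Replicate 1 had 14753 peaks covering 12728 kb, and replicate 2 had 25027 peaks covering 12884 kb. Median peak width was 796 bp in replicate 1 (quartiles 674 and 972 bp) and 455 bp in replicate 2 (quartiles 373 and 594 bp), so the longer list covered about the same length of genome with narrower peaks. Median scores were 81.3 and 87.6. Both lists had peaks on the 19 autosomes and on chromosomes X and Y. The lists give no read numbers, so it is not known whether the longer list came from the deeper library.

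The first question was which Pitx1 ChIP peaks recurred between the libraries. Of the replicate 1 peaks, 10300 (69.8%, 95% Wilson interval 69.1 to 70.6%) overlapped a replicate 2 peak. Of the replicate 2 peaks, 10658 (42.6%, interval 42.0 to 43.2%) overlapped a replicate 1 peak. Merged, these made 10274 replicated Pitx1 regions with a median length of 860 bp, covering 9706 kb. Rotating the lists within chromosomes gave a mean overlap of 1.39% of replicate 1 peaks and 0.830% of replicate 2 peaks. The observed overlaps were 50.4 and 51.3 times higher, and none of the 1000 rotations came near either (at most 1.77% and 1.06%; one-sided permutation p = 0.001 for each, the smallest the rotations can give). The remaining 4453 peaks of replicate 1 and 14369 peaks of replicate 2 were called in 1 library only. Regions are named after the antibody. Recurrence alone does not tell Pitx1 binding from chromatin that is pulled down with any antibody.

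Strong peaks recurred far more often than weak ones. In the highest score decile, 99.3% of replicate 1 peaks and 95.0% of replicate 2 peaks were shared. In the lowest decile the shares were 42.8% and 15.5%. Even there they lay above the overlap by rotation of the whole lists. The median score of shared peaks was 97.2 in replicate 1 and 145 in replicate 2, against 64.1 and 71.6 for unshared peaks. A small number of strong peaks did not recur, 11 in the highest decile of replicate 1 and 125 in that of replicate 2. The strongest unshared peak of replicate 2 was on chromosome 5 from 119279083 to 119279915 (score 925, rank 199). The nearest replicate 1 peak was 11.05 kb away. The strongest unshared peak of replicate 1 was on chromosome 8 from 115430469 to 115431241 (score 331, rank 648), 18.6 kb from the nearest replicate 2 peak.

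**Figure D1:**
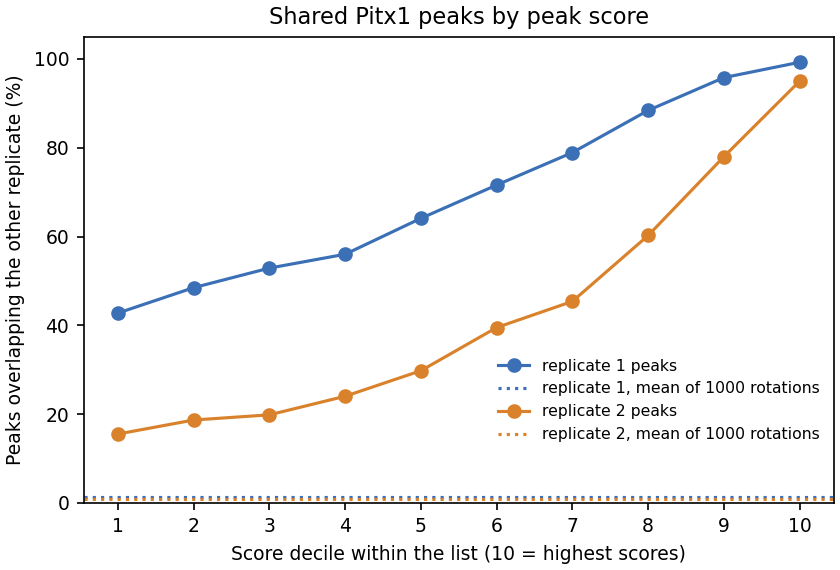
Percentage of peaks in each replicate that overlapped a peak of the other (y axis), by decile of peak score within the list (x axis, 10 is highest). Points are single lists without error bars and dotted lines are means of 1000 rotations; sharing rose from 42.8 to 99.3% in replicate 1 and from 15.5 to 95.0% in replicate 2.

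Peak strength was moderately correlated between the libraries, as seen only in peaks that were called in both. Across 9891 peaks paired 1 to 1, Spearman's rho between scores was 0.555 (bootstrap interval 0.540 to 0.568), and Pearson's r of log10 scores was 0.643. Both describe these libraries across peaks, which are not independent replicates. Midpoints of these pairs, which were chosen because they overlap, differed by a median of 58 bp. Replicate 1 peaks were the wider in 9133 pairs (92.3%), by a median of 1.45 times. In 369 replicated regions more than 1 replicate 2 peak fell together, against 26 regions for replicate 1.

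**Figure D2:**
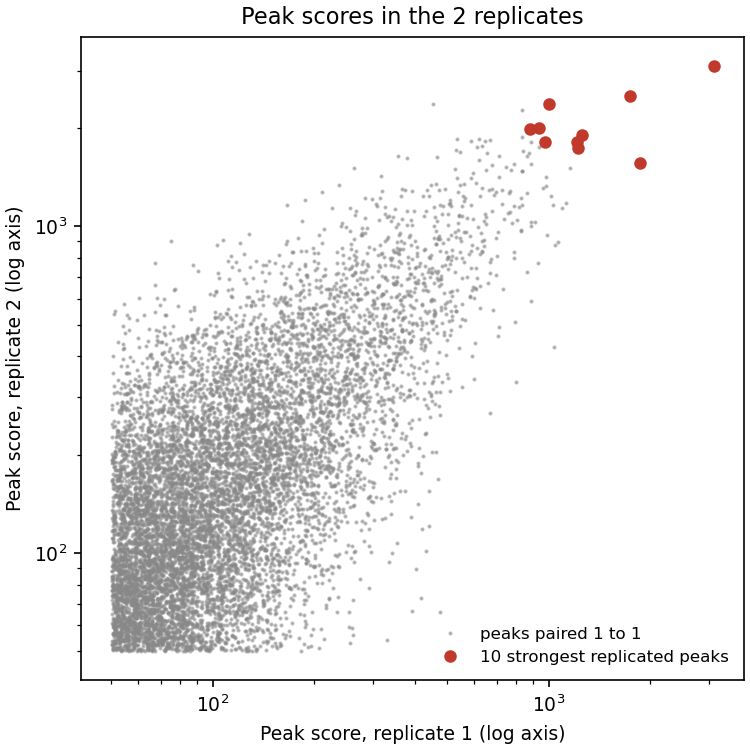
Peak score in replicate 1 (x axis) against replicate 2 (y axis), both on log axes, for 9891 peaks paired 1 to 1 (grey) and the best scores of the 10 strongest replicated regions (red). Scores rose together, with Spearman's rho of 0.555, and spread widely at the low end.

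The strongest replicated region spanned 6119 bp on chromosome 17, from 39979780 to 39985898. It was the only peak at the highest score, 3100, in either list, and also the widest peak of each list. It stood alone, with the nearest other replicated region 2731 kb away. Both lists gave it the same highest score, which may be a ceiling of the score. Repeated sequence was not screened for here, so whether this region reflects Pitx1 binding was not tested. The second was on chromosome 7 from 106104581 to 106107325, with scores of 1750 in replicate 1 and 2501 in replicate 2. The third was on chromosome 16 from 57694327 to 57696052 (scores 1256 and 1903), and the fourth on chromosome 7 from 83921650 to 83923491 (scores 1003 and 2369). Chromosome 3 held the next pair, from 55299180 to 55301853 (scores 1215 and 1813) and from 66547867 to 66549451 (scores 1222 and 1744). The others were on chromosome 12 from 37518729 to 37521556 (935 and 1998), chromosome 4 from 54482179 to 54484673 (1865 and 1561), chromosome 5 from 132559416 to 132560630 (977 and 1814) and chromosome 19 from 14964793 to 14966022 (881 and 1985). These regions differed in their surroundings. The chromosome 3 region at 55299180 had 11 other replicated regions within 100 kb, and those at 106104581 on chromosome 7 and 66547867 on chromosome 3 had 6 each. The regions on chromosomes 16, 17 and 19, and the one at 83921650 on chromosome 7, had 0. By midpoints within 250 bp in place of overlap, 3 of the 10 would not count as replicated, namely those at 106104581 on chromosome 7, 55299180 on chromosome 3 and 37518729 on chromosome 12. Positions in the order also moved when either library was ranked alone. The chromosome 19 region was at rank 33 in replicate 1 and 7 in replicate 2, and the chromosome 4 region at 2 and 33.

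Replicated Pitx1 regions were spread over all autosomes, at 3.14 per Mb on chromosome 7 (95% Poisson interval 2.87 to 3.43) up to 5.05 per Mb on chromosome 18 (4.60 to 5.54). Chromosomes 3, 13 and 11 followed chromosome 18, with 4.80, 4.74 and 4.69 per Mb. Chromosome X had 128 regions, or 0.769 per Mb (0.642 to 0.914), against 4.11 per Mb over the autosomes. The ratio of X to autosome density was 0.187 (exact interval 0.156 to 0.223). It was 0.198 in replicate 1 alone (194 peaks on X) and 0.180 in replicate 2 alone (300 peaks on X). Chromosome Y had 1 replicated region. Lengths up to the last peak include stretches that reads cannot be placed on, and no correction was made for these.

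**Figure D3:**
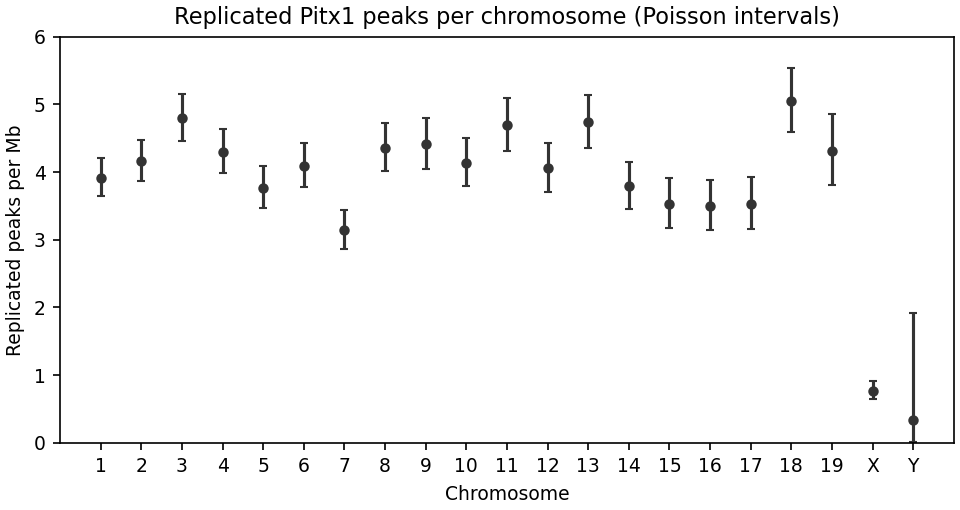
Replicated Pitx1 regions per Mb (y axis) on each chromosome (x axis), with 95% exact Poisson intervals that cover counting error only. Autosomes lie between 3.14 and 5.05 per Mb, and chromosome X at 0.769.

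Replicated Pitx1 regions formed more clusters than uniform placement gave, although most regions lay outside clusters. Neighbouring regions were a median of 89.9 kb apart, against 164 kb when the same number was placed uniformly. There were 187 clusters of 3 or more regions under 10 kb apart, which held 614 regions (5.98%). Uniform placement gave a mean of 17.2 clusters and at most 32, so the observed count was 10.8 times higher (permutation p = 0.001, the smallest possible). Regions that did not overlap were counted separately however close, so 1 stretch split by the caller can count more than once. No alternative merged close neighbours. Uniform placement also reaches sequence that reads cannot be placed on. These limits hold for the windows below too. Most clusters were small: 144 had 3 regions, 36 had 4 and 6 had 5. The largest had 8 regions within 24.2 kb, on chromosome 18 from 55133508 to 55157669. The number of clusters depends on the list, with 338 in replicate 1 alone and 1135 in replicate 2 alone. Each was above uniform placement, by 6.96 and 5.16 times (permutation p = 0.001 for each).

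The densest window of 200 kb held 17 replicated regions, on chromosome 18 from 54987491 to 55188963, which includes the largest cluster. At the average rate of that chromosome 1.01 would fall in a window. The second, on chromosome 6 from 50931251 to 51132171, held 16. The third was on chromosome 13 from 60092081 to 60279578, with 15, and the fourth on chromosome 3 from 55184257 to 55342490, with 14. The fourth window contains the fifth strongest region. The fifth, on chromosome 11 from 111509091 to 111706348, held 13. Uniform placements of the regions reached at most 10 in any window of the genome (permutation p = 0.001 for each window). The windows were chosen for regions present in both libraries, so peaks of each were bound to lie in them. Replicate 1 alone had 23, 18, 17, 19 and 13 peaks in them, in the same order, and replicate 2 alone had 30, 26, 18, 20 and 18.

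**Figure D4:**
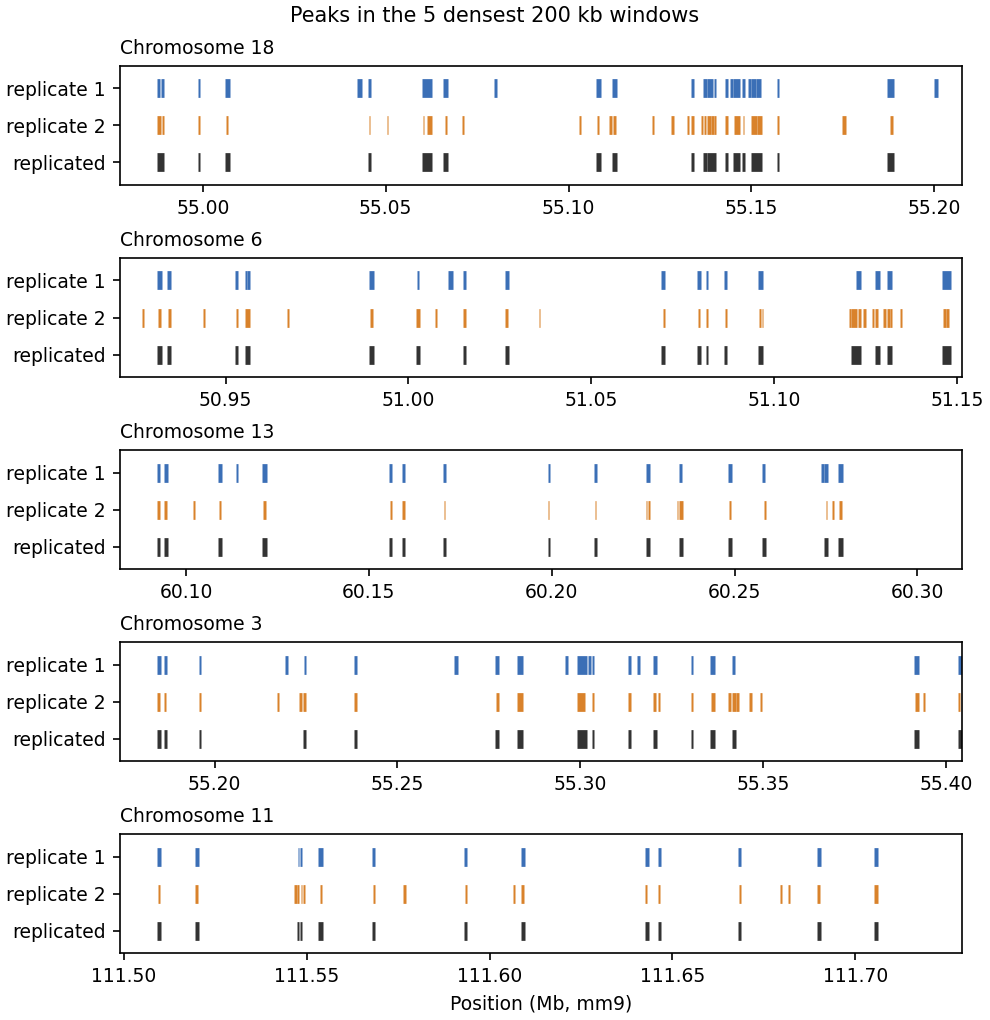
Peaks of replicate 1 (blue), replicate 2 (orange) and replicated regions (black) in the 5 densest windows, drawn to scale over 230 kb of each chromosome (x axis, position in Mb, mm9). The chromosome 18 window holds 17 replicated regions, several of them within a cluster of 24.2 kb near 55133508.

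An additional list, deposited by the authors beside the replicate 1 peaks, gave 10625 positions of 1 bp in the copy used here. Each lay inside a different replicate 2 peak that was shared with replicate 1, and 10491 (98.7%) also lay inside a replicate 1 peak. The positions were a median of 46 bp from the midpoint of the replicate 2 peak. They covered 99.7% of the 10658 shared replicate 2 peaks. The 33 shared peaks without a position had a median score of 1813 in replicate 2, against 145 for those with one. None of the 10 strongest replicated regions named above contained a position.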

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

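No paired analysis was possible because the input libraries, which share the replicate numbers, have no list of peaks. The overlap between replicates and the excess of clusters over uniform placement kept their direction and permutation p = 0.001 under every alternative run. Sharing ranged from 57.4 to 76.5% of replicate 1 peaks and from 34.0 to 58.5% of replicate 2 peaks. With equal numbers of best peaks from each list it was 57.4% in replicate 1 and 58.5% in replicate 2. Most overlaps pair 1 peak with 1 peak, so lists of equal length are bound to give close shares. The closeness therefore does not bear on whether the replicates differ. The number of replicated regions fell to 5486 in the best 50% of each list by score and to 2821 in the best 25%, which hold fewer peaks. Spearman's rho was 0.520 in the best 25% and 0.586 with reciprocal overlap of 50%; the cause was not tested. With midpoints within 250 bp in place of overlap, 87.6% of the listed positions met a replicate 1 peak and 96.2% a replicate 2 peak. The X to autosome ratio was 0.147 in the best 50%, and between 0.160 and 0.201 otherwise. Clusters numbered 54 in the best 50%, 118 with equal numbers of best peaks, 117 with reciprocal overlap, 55 with gaps under 5 kb and 487 with gaps under 25 kb. With each replicate left out in turn they numbered 338 to 1135. In the best 50%, the 5 densest windows, in the order given in the report, held 11, 7, 7, 8 and 8 regions, so their order changed too. The ratio to uniform placement stayed between 5.16 and 20. The tests planned against genes and sequence, their alternatives, and reciprocal overlap with 1 bp positions were not run. Unknown read depth limits any statement on peaks called in 1 library only.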

Other observations

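Peak density per chromosome was planned before the data were examined. The use of X to autosome ratios in single replicates to weigh an explanation was not. It was chosen after the results it bears on, or closely related values, had been seen. The same holds for the tests of unshared peaks, of strength in clusters, of the list of positions and of X copy number. Pitx1 peaks found in replicate 1 only lay near other peaks somewhat more often than after rotation, although most lay farther away. Of the 4453 unshared replicate 1 peaks, 485 (10.9%) lay within 5 kb of a replicated region, 2.39 times the mean of 1000 rotations (4.55%, permutation p = 0.001). Another comparison set them against unshared replicate 2 peaks, which by definition they do not overlap: 481 (10.8%) were within 5 kb of one, 1.8 times the mean of rotations (5.99%, permutation p = 0.001). Replicated regions in clusters were also somewhat stronger than all those outside clusters, whether isolated or not. The median rank percentile by summed rank, where lower is stronger, was 41.7 in clusters against 50.5 outside, a difference of -8.86 (two-sided permutation p = 0.001, the smallest possible). The order was the same by replicate 1 ranks (42.5 against 50.5) and by replicate 2 ranks (42.7 against 50.4). The permutation treats regions as independent, which neighbouring regions are not.

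The list of positions leaves out most of the strongest peaks. Of the 33 shared replicate 2 peaks without a position, 97.0% (32 of 33) overlapped or were among the 20 best scores of either replicate, where random draws of 33 shared peaks held at most 2. The value of 20 was chosen after the scores were seen, so this restates the gap in scores and does not test a cause. Removal by width alone is argued against, since of the 33 widest shared peaks outside the 100 best scores, 0 lacked a position. The peaks without a position were wide, at a median width percentile of 97.0 in replicate 2, where higher is wider. Most of them were among the 100 best scores of that list, where width and score were not separated. A candidate explanation is that the highest scores of each list were set aside when the list was made, by a step that is not given in the sources used here. Another is that the copy used here is incomplete, which no value in the lists decides. Both stay open. In replicate 2 the split by score was clean at the top. Its 19 best peaks all lacked a position, down to a score of 1749.85, and the highest score with a position was 1749.19. Some other peaks go against a plain score limit. In replicate 1, 3 of the 20 best peaks have a position through their replicate 2 partners, although the peak of rank 19 lacks one. Also, 1 of the peaks without a position was outside the 20 best of both lists. That peak, on chromosome 6 from 51121131 to 51122700, is 1570 bp wide and scored 51.00 in replicate 2 (rank 24418 of 25027), with a replicate 1 partner at 295 (rank 822 of 14753, within the highest score decile), so a limit at the 20 best scores cannot account for it. In replicate 2, the peak of rank 21 (score 1744) lacks one, and its replicate 1 partner is at rank 6. No biological explanation was tested.

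That 30.2% of replicate 1 peaks were unshared may come from weak peaks that miss the score threshold in the other library. The rise in sharing of 56.5 percentage points from the lowest to the highest score decile prompted this explanation and does not test it, and signal below the threshold was not analysed here. Placement of all unshared replicate 1 peaks at random along whole chromosomes is argued against by the ratio of 1.8 given above. Random placement within mappable or accessible sequence stays open, because rotation does not keep to such sequence. Also open is whether the unshared peaks are weak Pitx1 binding or accessible chromatin that is pulled down with any antibody, because a ChIP with a control antibody was not analysed here. The same question is open for shared peaks, since such chromatin could recur in both libraries. The group design holds no second condition, so no biological explanation was tested.

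Chromosome X had 0.187 times the autosomal peak density. Low signal in 1 library only is argued against by the ratio of 0.198 in replicate 1, close to that of replicate 2 (0.180). Fewer copies of chromosome X in chromatin from male embryos could contribute. If scores on X were halved, 0.367 of the autosomal density would be left in replicate 1 and 0.425 in replicate 2, by the share of autosomal peaks with at least 2 times the lowest score. Both are more than the ratios seen. These values rest on scores that scale with copy number, which the caller's background need not follow, and the share of male embryos is not given, so copy number cannot be told apart from a shortage of mappable sequence or of Pitx1 sites on X. Of the X peaks that were called, 42.7% were shared in replicate 2, against 42.6% of autosomal peaks, and 66.5% against 69.9% in replicate 1; these differences were not tested.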
